A study of Mus musculus with 27 samples.

How the data were processed

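RNA was measured in whole uterus of ovariectomised female mice of 3 kinds: C57BL/6 (B6), C3H and their first-generation hybrid (F1). Per the labels' protocols, animals aged 8 weeks rested for 1 to 2 weeks after removal of the ovaries and then received one intraperitoneal injection. It held either 17β-estradiol (E2, the main ovarian estrogen) at 40.0 µg per kg body weight in 0.1 ml saline with 0.25% ethanol, or the saline and ethanol vehicle alone. Uteri were taken 2 h or 24 h after injection, and the labels give no time for the vehicle samples. There were 9 groups (3 strains by vehicle, E2 2 h and E2 24 h) with 3 samples each, 27 arrays in all. Tissue came from 3 animals per treatment group, but the labels do not tie an array to an animal, so p-values measure only the spread between these samples.

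Cy3-labelled cRNA was made from 500 ng total RNA, and 1.65 µg of it was hybridised for 17 h to Agilent 1-colour whole mouse genome arrays with 4 arrays per slide, per the labels' protocols. The deposited scanner files hold spot intensity on a linear scale: a raw mean, a local background median and a processed signal. Per the file headers, the processed intensity was background-subtracted and spatially detrended within each array by Feature Extraction 9.5.3.1, which replaces low values by surrogates and does not scale arrays to each other. The submitters' processing notes name Agilent Feature Extraction 9.5. The deposited value table of the series held the same intensity values as the processed signal in 27 of 27 columns, with column medians over all spots from 120.2 to 160.7. Probe coordinates in the files are on mm7, and none are given here, because the gene table used for names has another assembly.

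Each array held 45018 spots, of which 1639 were control spots and were left out. Spots with an outlier mark were dropped (48 to 117 per array), saturated spots were kept (0 to 8 per array), and 4286 to 6886 spots per array held a surrogate. Spots of one probe were averaged, since 245 probes were spotted 10 times, giving 41174 probes. Gene names came from the files' accessions through a RefSeq gene table used only for names. The accession named 22951 probes, the file's symbol 6659 and a synonym 3097, and 8467 kept the file's own name. The name differed from the one in the file for 8238 probes. Log2 processed signal minus each array's 75th percentile was the measure throughout, so a level of 0 is that percentile. Of the probes, 32901 were well above background on all arrays of at least 1 group. For a gene with several such probes, the probe with the highest mean signal was taken, and 7484 of the 21872 genes tested had more than 1. A symbol was known for 16029 genes, and 46 genes had a missing value on some array. No level of one probe is set against that of another.

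Where a gene was not well above background on every array of a group, a fold is given as "at least". It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. For differences between responses of such a gene, the fitted value is given with a statement that a group was not well above background.

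One linear model of 9 group means over all 27 arrays was fitted with limma 3.58.1 (lmFit and eBayes, 18 residual and 1.96 prior degrees of freedom) in R 4.3.3 and the data.table package (version 1.17.8). The 15 contrasts were E2 against vehicle at 2 h and 24 h in each strain, strains against each other in vehicle, and the difference of the E2 response between strains at each time. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast, and errors beside log2 changes are limma standard errors (SE). Values were read and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

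Gene lists were tested with camera (limma) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 31 lists of at least 5 measured genes. Of 545 list entries, 521 were measured. They covered 17 processes or gene families and the markers of 14 cell types or tissues, each named with its results. A pair of genes with known strain differences (H2-Ea and Nnt) checked the strain labels. Lists of liver transcripts and of squamous epithelium were added after the data had been seen and were not tested with camera.

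Response size was scored per E2 array as the mean log2 change from the strain's own vehicle mean. The genes were those called in the strain not being compared with at least a 2-fold change, signed by their direction there. Strains were compared by exact two-sided permutation within E2 and within vehicle arrays (400 relabellings), so vehicle differences also enter p. The position of F1 between the parents was the slope of F1 minus B6 on C3H minus B6 over genes differing between the parents, set beside 20 simulated data sets with F1 at B6, at the midpoint and at C3H.

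The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 8 largest rises and falls by mean change over 3 strains among genes with a symbol called with one sign in all 3, for E2 against vehicle at each time. It takes the 10 largest differences each way for C3H against B6 in vehicle and in response, and the 4 largest each way for contrasts with F1. It adds up to 3 called members of each list with the largest changes, or the brightest member where none was called. Esr1, Pgr, Ltf, Igf1, C3, Runx1, H2-Ea and Nnt are always taken. Members of the kallikrein 1 family beyond these, liver transcripts and squamous genes were chosen after their values had been seen.

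The 27 arrays lay on 7 slides. Slides 1 to 3 and 4 to 6 share no group across the divide and slide 7 holds only F1 E2 24 h, so 5 contrasts could be fitted with slide as a fixed term. These 5 cannot be fitted without B6 E2 2 h replicate 1 or F1 vehicle replicate 3, nor can 6 of the 8 with lot without the latter, and the lone array is assumed to vary like the other groups. All contrasts were also fitted with slide as a random block, and 8 contrasts with F1 with the lot of the slides (slides 6 and 7 against the rest) as a fixed term.

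The method was tested on simulated data with 200 of 21872 genes changed. For E2 24 h against vehicle in C3H, 37.3% of genes changed by 0.5 log2, 76.1% of those changed by 1 and 98.5% of those changed by 2 were called, with 10 unchanged genes called. For the difference of C3H and B6 responses at 24 h these shares were 16.4%, 59.7% and 89.4%, with 12 unchanged genes called. In the first contrast camera recovered a list shifted by 0.5 at 0.460 (adjusted p = 7.12e-66), with 0 others of 31 called. Lists of correlated genes were not tested. A C3H response at 24 h made at 80% of the B6 response was recovered at 80.2% (permutation p = 0.075), so such a difference can be missed at 0.05.

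Alternatives were normexp background correction (offset 50) of the raw means with quantile normalisation, quantile normalisation of the processed signal, median centring, and the unscaled deposited value table. Further ones were no filter on dim probes, a filter over all 27 arrays, kept outlier spots, the mean over a gene's probes, eBayes with trend and robust fitting, array weights, models of only the strains compared, slide and lot terms and the replicate number as a block. A 2-fold minimum, fry in place of camera, response scores without a fold minimum and, for genes and scores, leaving out each array in turn completed the set. Leaving out together 3 arrays that stood apart, leaving out each array in turn for the gene lists, tests within slide 1 and slide 6, and the tests of slide, scaling alone, probe mismatch, paralogs and liver RNA weighed at the end were added after the data had been seen.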

Results

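Uterine RNA of ovariectomised B6, C3H and (B6 × C3H)F1 females was profiled after vehicle, 2 h after estradiol (E2) and 24 h after E2, on 3 arrays per group. The comparisons ask whether the uterine response to E2 depends on strain. Each array measured 41174 probes, and 21872 genes were tested. Between 72.4% and 79.4% of probes per array were well above background, and the 75th percentile of the processed signal lay between 1211 and 1579 intensity units. Values across genes of replicate arrays correlated at r = 0.988 to 0.996. The first 3 principal components held 38.6%, 27.1% and 14.3% of the variance over 21826 genes. In 3 arrays more than 250 genes lay over 1 log2 unit from their group mean, namely C3H E2 24 h replicate 1 (494 genes), B6 vehicle replicate 1 (436) and C3H E2 2 h replicate 1 (296).

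H2-Ea and Nnt served as a check of the strain labels. H2-Ea, an MHC class II gene whose product B6 mice lack, was at least 4.08-fold higher in C3H than in B6 vehicle uterus and at least 2.13-fold higher in F1. Nnt, a mitochondrial transhydrogenase gene that carries a deletion in one widely used B6 substrain, was higher by 1.03 log2 (SE 0.07) in C3H and by 0.62 in F1. With E2 these 2 genes gave 0 higher and 0 lower in B6, 0 and 1 in C3H and 0 higher and 1 lower (0 and 2 adjusted over the list alone) in F1 at 2 h. At 24 h they gave 1 higher and 0 lower, 1 higher and 0 lower and 1 higher and 1 lower.

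**Figure D1:**
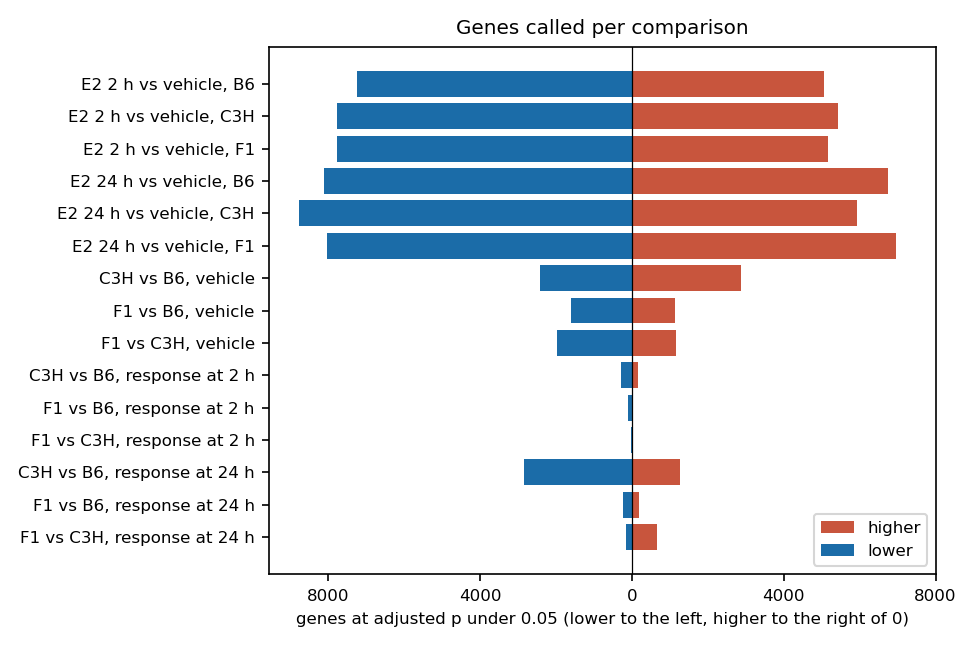
Genes called at adjusted p under 0.05 in each of the 15 contrasts, with lower genes to the left and higher genes to the right of 0 on an axis of gene counts.

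The effect of E2 was taken first at 2 h after injection. The largest rises shared by the 3 strains were in Klk1b5, a tissue kallikrein protease, which rose by 8.36, 7.5 and 7.59 log2 in B6, C3H and F1 (SE 0.29, n = 3 arrays per group), or 329-, 181- and 193-fold. The hair keratin genes Krt87 (7.82, 6.66 and 7.53) and Krt86 (7.69, 6.8 and 7.27) rose nearly as much. Gdf15, a stress-induced cytokine of the TGF-β family, rose by 6.51, 6.52 and 7.03, the immediate early transcription factor gene Egr4 by 7.03, 5.53 and 6.14 and the aggrecanase gene Adamts4 by 5.75, 6.27 and 5.86. Trim15 rose at least 63.9-fold in B6, 43.7-fold in C3H and at least 75.3-fold in F1. Gad2, a glutamate decarboxylase gene, rose at least 15-, 17.5- and 16.6-fold.

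Among the largest falls at 2 h were Ptgfr, the receptor for prostaglandin F (−4.13, −3.64 and −4.13, SE 0.17), the transcription factor gene Msc (−4.63, −3.0 and −4.13), the pro-apoptotic gene Bmf (−3.59, −3.64 and −4.07) and Hgf, a growth factor gene of stromal cells (−3.89, −3.36 and −3.85). The lactate receptor gene Hcar1 fell at least 13.1-, 9.58- and 8.21-fold, the transporter gene Slc38a11 at least 11.4-, 14.2- and 11.4-fold and the neuropeptide Y receptor gene Npy2r at least 3.25-, 5.68- and 2.97-fold. Slco4c1, an organic anion transporter gene, changed by −2.93 in B6 and −3.98 in F1 and fell at least 16.5-fold in C3H. The largest adjusted p (limma) among the genes named in these opening paragraphs was 2.52e-06 (Trim15 in C3H).

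Counts adjusted over the list alone follow in square brackets wherever they differed from those over all genes. Of 29 early estrogen-response genes, 28 rose and 1 fell in B6, 26 rose and 3 fell in C3H, and 26 rose and 1 fell in F1. Their median changes were 3.02, 2.8 and 2.67 (camera adjusted p = 4.67e-20, 2.62e-15 and 1.33e-16). The immediate early gene Fos rose by 5.21, 5.62 and 5.18, the activin subunit gene Inhbb by 4.73, 4.87 and 4.74 and the growth arrest gene Gadd45g by 4.38, 4.44 and 4.45. This list alone kept its call in all 3 strains with estimated correlation (adjusted p = 0.00371, 0.0145 and 0.00979).

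Ribosome biogenesis genes moved upward together at 2 h, with 20 higher and 1 lower in B6, 19 and 2 in C3H and 22 and 0 in F1 of 25, and medians of 0.59, 0.57 and 0.73. Camera gave adjusted p = 2.84e-08, 4.02e-07 and 1.04e-09, and 0.692, 0.945 and 0.477 with estimated correlation. Rrs1 rose by 1.94, 1.93 and 2.07, the nucleolar gene Gnl3 by 1.77, 1.74 and 1.69 and the helicase gene Ddx21 by 1.69, 1.66 and 1.81. Of 13 heat shock genes, B6 had 8 higher and 0 lower [9 and 1], C3H 10 and 0 and F1 9 and 0. The chaperone gene Dnajb1 stood at 1.02, 1.27 and 1.51. Camera called the list in each strain (adjusted p = 0.0461, 0.00436 and 0.000704, and 0.932, 0.951 and 0.68 with estimated correlation). In B6 the call was lost without E2 replicate 1 (adjusted p = 0.0872) or vehicle replicate 2 (0.0676). Of 22 genes of protein folding in the endoplasmic reticulum, B6 had 11 higher and 2 lower, C3H 13 and 1 and F1 14 and 1. Camera called them in C3H (adjusted p = 0.00447) and F1 (0.000704), not in B6 (0.105), and with estimated correlation adjusted p = 0.988 in C3H and 0.987 in F1. The stress regulator gene Atf4 rose by 2.38, 2.36 and 2.43 and the chaperone gene Hspa5 by 0.91, 1.15 and 1.29.

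Mitosis genes were called as a list at 2 h in F1, with 17 higher and 0 lower [18 and 0] of 25 (median 0.57, adjusted p = 0.000704, and 0.987 with estimated correlation). In B6 there were 3 higher and 0 lower [2 and 0] and in C3H 3 higher and 0 lower (median −0.01, mean 0.24). Mad2l1, a spindle checkpoint gene, rose by 4.57, 4.5 and 4.55. DNA replication gave 4 higher and 6 lower [2 and 5] of 25 in B6, 3 and 8 [3 and 7] in C3H and 11 and 5 in F1 and were not called by camera.

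Genes of water and ion transport went both ways, with 6 higher and 8 lower [6 and 9] of 22 in B6, 6 and 11 [7 and 11] in C3H and 6 and 9 in F1. The median was −0.32 in B6 while the mean was 0.41 and camera pointed upward (adjusted p = 0.574), and C3H and F1 showed the same split of signs. The water channel genes Aqp5 (5.14, 5.91 and 5.43) and Aqp8 (3.93, 4.35 and 4.79) and the sodium channel gene Scnn1a (2.02, 2.56 and 1.78) rose. Angiogenesis gave 10 higher and 10 lower of 24 in B6, 10 and 10 in C3H and 10 and 8 [10 and 9] in F1, with medians of −0.15, −0.14 and −0.04 beside means of 0.64, 0.46 and 0.57 and camera upward at adjusted p = 0.302, 0.571 and 0.269. The vascular growth factor genes Pgf (6.17, 5.36 and 5.67) and Vegfa (3.35, 3.06 and 2.95) and the adrenomedullin co-receptor gene Ramp3 (4.05, 4.47 and 4.03) rose. Steroid receptor and coregulator genes gave 11 higher and 8 lower of 22 in B6, 10 and 11 in C3H and 10 and 9 in F1, with medians of −0.11 and −0.08 beside means of 0.08 and 0.15 in C3H and F1. Greb1 rose by 4.05, 3.69 and 3.65, the corepressor gene Nrip1 by 2.53, 2.37 and 2.39 and the progesterone receptor gene Pgr by 1.61, 1.66 and 1.99 (SE 0.08), while the hedgehog receptor gene Ptch1 fell (−2.61, −3.5 and −3.1). The estrogen receptor gene Esr1 fell in C3H (−0.60) and F1 (−0.39, where its probes disagreed in sign) and stood at −0.29 in B6 (adjusted p = 0.0778).

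RUNX family genes gave 2 higher and 2 lower of 5 in B6, 3 and 2 in C3H and 2 and 2 in F1, with medians of 0.20, 0.28 and 0.18 against means of −0.58, −0.67 and −0.64. Runx1 rose by 0.31, 0.34 and 0.53, whereas Runx1t1 (−2.55, −3.09 and −2.74) and Runx2, a regulator of bone formation (−1.18, −1.64 and −1.52), fell. WNT pathway gave 5 higher and 9 lower of 23 in B6, 4 and 11 in C3H and 4 and 10 in F1. The ligand genes Wnt4 (3.34, 2.8 and 3.19) and Wnt7b (2.01, 2.32 and 2.17) rose and the receptor gene Fzd1 (−3.2, −3.23 and −3.1) fell. Extracellular matrix gave 7 higher and 9 lower [7 and 10] of 28 in B6, 6 and 11 in C3H and 8 and 10 [9 and 10] in F1. Their median was −0.15 in C3H and −0.05 in F1, while the mean was 0.03 and 0.06 and camera pointed down in C3H and up in F1. The hyaluronan synthase genes moved apart, Has1 upward (4.7, 5.89 and 5.54) and Has2 downward (−3.4, −2.92 and −3.13).

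Chemokine and cytokine genes gave 3 higher and 5 lower [3 and 4] of 28 in B6, 10 and 5 in C3H and 8 and 4 in F1, and in C3H the median was −0.14 while the mean was 0.36 and camera pointed upward. The neutrophil chemokine gene Cxcl1 rose in C3H (3.63) and F1 (2.9) and stood at 1.29 in B6 (adjusted p = 0.0814). Interferon-induced genes gave 1 higher and 12 lower of 21 in B6, 1 and 7 [1 and 5] in C3H and 2 and 6 [2 and 5] in F1. The antiviral genes Ifit2 (−1.55, −1.72 and −1.65) and Rsad2 (−1.7, −1.58 and −2.01) fell. The 21 genes averaged 1.25 in B6 vehicle replicate 1 and −0.20 and −0.25 in the other B6 vehicle arrays, as log2 differences from the mean of all arrays. Apoptosis gave 9 higher and 9 lower [9 and 10] of 28 in B6, 9 and 8 in C3H and 11 and 10 in F1 (median −0.03 and mean 0.03 in B6). The survival gene Bcl2l1 rose (1.16, 1.26 and 0.95) and the death gene Bbc3 fell (−1.17, −1.64 and −1.62). Stroma markers gave 2 higher and 9 lower of 12 in B6, 3 and 8 [3 and 9] in C3H and 3 and 9 in F1. Hoxa10 (−1.64, −1.88 and −1.78) and Nr2f2 (−2.07, −2.28 and −2.02) fell and Twist2 (2.5, 2.35 and 2.54) rose.

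At 2 h E2 changed 12298 genes in B6 (5057 higher and 7241 lower), 13190 in C3H (5436 and 7754) and 12947 in F1 (5173 and 7774). In all 3 strains 9932 genes changed with one sign, 4009 higher and 5923 lower. Log2 changes correlated across genes, which are not independent replicates, at r = 0.869 for B6 and C3H, 0.918 for B6 and F1, and 0.918 for C3H and F1, with no arrays shared between strains. The median change of all genes was −0.10 in C3H, and the split of calls moved with the centring. Median centring gave 6668 higher and 5906 lower in C3H and 6358 and 5948 in F1, and the unscaled deposited values 6660 and 5177 in C3H and 7163 and 4664 in F1. With slide as a fixed term 9309 genes were called in B6, the same value as within slide 1 (1 E2 array and 3 vehicle arrays), and 10571 in F1, as within slide 6 (3 and 1). The early estrogen-response medians were then 3.00 and 2.86 and those of ribosome biogenesis 0.58 and 0.76. The C3H contrast has no slide with both groups, and with lot as a fixed term F1 had 10295 genes, resting on F1 vehicle replicate 3.

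At 24 h other genes led the shared rises. Among cornified envelope genes of the small proline-rich family Sprr2f rose by 8.4, 5.82 and 5.79 log2 (SE 0.33), or 338-, 56.3- and 55.3-fold in B6, C3H and F1, and Sprr1a by 6.45, 4.78 and 5.25. Sprr2d rose at least 133-fold in B6 and by 5.96 and 7.07 in C3H and F1. The chitinase-like gene Chil1 rose by 5.5, 6.94 and 5.1, the secreted-protein gene Fam3b by 6.08, 4.27 and 5.85, the diamine oxidase gene Aoc1 by 5.77, 4.19 and 5.68 and the serpin gene Serpinb5 by 5.4, 5.25 and 5.61. Atp13a4, an ion-transporting ATPase gene, rose at least 14.4-, 13.1- and 10.8-fold.

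Among the largest falls at 24 h were Coch, an extracellular matrix gene (−5.52, −5.17 and −5.12, SE 0.20), the methyltransferase gene Inmt (−4.49, −5.02 and −4.05), the retinoic acid-forming enzyme gene Aldh1a3 (−4.24, −4.36 and −3.84) and the melanocyte gene Mlana (−4.24, −4.15 and −3.99). The chloride channel gene Ano2 fell at least 38.6-fold in B6 and changed by −5.91 and −5.44 in C3H and F1, and Lgi1 changed by −4.33 in B6, −3.64 in C3H and fell at least 14.3-fold in F1. Kcnip2, a potassium channel subunit gene, fell at least 12.4-, 10.1- and 9.39-fold. Cadps, a gene of vesicle release, fell at least 9.51-fold and 4.29-fold in B6 and F1 and changed by −3.55 in C3H. The largest adjusted p (limma) among the 24 h genes named so far was 7.13e-06 (Chil1 in F1).

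The cell division lists rose together at 24 h. All 25 mitosis genes rose in each strain, with medians of 3.05 in B6, 2.56 in C3H and 3.27 in F1 (camera adjusted p = 2.82e-13, 1.45e-15 and 3.3e-15, and 0.374, 0.354 and 0.338 with estimated correlation). Cyclin B1 (Ccnb1) rose by 4.18, 3.16 and 4.71, the survivin gene Birc5 by 3.68, 2.86 and 4.02 and the ubiquitin-conjugating gene Ube2c by 3.55, 3.18 and 4.17. DNA replication gave 24 higher and 0 lower of 25 in B6, 23 and 0 in C3H and 25 and 0 in F1, with medians of 1.77, 1.14 and 1.7. Camera gave them adjusted p = 5e-14, 1.8e-12 and 2.33e-14, and 0.158, 0.257 and 0.169 with estimated correlation. The replication factor genes Mcm10 (3.87, 2.72 and 4.19) and Cdc6 (3.69, 2.41 and 3.87) and the DNA methylation cofactor gene Uhrf1 (3.56, 2.19 and 3.8) rose.

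Late estrogen-response and secretory genes gave 17 higher and 0 lower of 22 in B6, 17 and 1 [18 and 1] in C3H and 18 and 1 in F1, with medians of 2.69, 3.23 and 3.22. Camera gave them adjusted p = 2.36e-07, 3.63e-10 and 7.21e-08, and 0.158, 0.13 and 0.169 with estimated correlation. At 2 h the same list had 5 higher and 4 lower in B6, 7 and 4 in C3H and 5 and 4 [5 and 3] in F1, with medians of −0.10 and −0.04 beside means of 0.26 and 0.38 in B6 and F1. The mucin gene Muc4 rose by 4.64, 4.3 and 4.07 and the lactoferrin gene Ltf by 2.75, 4.34 and 3.35, after a fall of Ltf at 2 h (−1.01, −0.73 and −1.13). Complement C3 rose in C3H (1.28) and F1 (1.27) and stood at 0.28 in B6 (adjusted p = 0.512). Igf1, a growth factor gene, rose by 1.89, 1.12 and 1.5, and Pgr by 0.99, 0.95 and 0.92. Esr1 changed by −0.57, −0.66 and −0.54, with probes that disagreed in sign. Early estrogen-response genes gave 10 higher and 9 lower of 29, 6 and 12 [5 and 11], and 8 and 10 at this time, with a median of −0.02 beside a mean of 0.01 in B6 and 0.03 beside −0.12 in F1.

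Ribosome biogenesis gave 24 higher and 0 lower [25 and 0] of 25 in B6, 22 and 0 in C3H and 23 and 0 in F1, with medians of 0.97, 0.39 and 0.58. Camera gave them adjusted p = 4.14e-09, 1.7e-05 and 9.05e-07, and 0.291, 0.645 and 0.454 with estimated correlation. Bop1 rose by 1.59, 0.86 and 1.33 and the fibrillarin gene Fbl by 1.35, 0.80 and 1.07. Protein-folding genes of the endoplasmic reticulum gave 17 higher and 4 lower [17 and 5] of 22 in B6, 15 and 4 [16 and 4] in C3H and 17 and 3 in F1. Camera gave them adjusted p = 0.000569, 0.00943 and 0.00115, and 0.656, 0.645 and 0.587 with estimated correlation. Sdf2l1 stood at 3.11, 2.28 and 2.82 and calreticulin (Calr) at 2.06, 1.58 and 1.62. Heat shock gave 9 higher and 2 lower [10 and 2] of 13 in B6, 5 and 1 [5 and 0] in C3H and 7 and 1 in F1, called in B6 (adjusted p = 0.0238, and 0.656 with estimated correlation). The mitochondrial chaperone genes Hspe1 (1.86, 1.28 and 1.44) and Hspd1 (1.51, 0.80 and 1.01) rose.

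WNT pathway genes moved downward at 24 h, with 2 higher and 16 lower of 23 in B6, 2 and 17 in C3H and 2 and 16 in F1. Camera gave them adjusted p = 0.00115, 0.0134 and 0.00596, and 0.158, 0.354 and 0.33 with estimated correlation. The WNT inhibitor gene Wif1 changed by −3.34, −4.36 and −3.62 and the ligand genes Wnt11 (−2.31, −1.76 and −2.33) and Wnt2 (−2.17, −1.84 and −1.94) fell as well. Steroid receptor and coregulator genes gave 5 higher and 14 lower of 22 in B6, 5 and 15 in C3H and 5 and 15 in F1. The hedgehog pathway genes Ptch1 (−2.31, −2.5 and −2.64) and Ihh (−2.19, −1.6 and −1.9) fell. Water and ion transport genes gave 12 higher and 7 lower of 22 in B6, 11 and 6 [11 and 7] in C3H and 12 and 7 in F1. The carbonic anhydrase genes Car12 (3.7, 3.09 and 3.2) and Car2 (3.27, 3.71 and 3.59) rose. Extracellular matrix gave 14 higher and 8 lower of 28 in B6, 14 and 8 in C3H and 17 and 8 in F1, with collagen I (Col1a1, 2.96, 2.56 and 2.61) and the protease inhibitor gene Timp1 (2.4, 2.37 and 2.65) up. Angiogenesis gave 7 higher and 12 lower of 24 in B6, 2 and 12 in C3H and 5 and 13 in F1. The vessel regulator gene Angpt2 fell (−1.19, −0.78 and −1.15). The RUNX list gave 2 higher and 2 lower of 5 in B6 (median 0.24, mean −0.25), 0 and 2 in C3H and 2 and 2 [3 and 2] in F1 (median 0.13, mean −0.21), with camera downward in all 3. Runx1 rose in B6 (0.35, with probes that disagreed in sign) and F1 (0.59) and stood at −0.02 in C3H (adjusted p = 0.897). Apoptosis gave 13 higher and 10 lower [14 and 10] of 28 in B6, 13 and 9 in C3H and 14 and 8 in F1. The survival gene Bcl2 fell (−1.86, −1.67 and −1.78).

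Cell type markers follow. Epithelial markers gave 13 higher and 1 lower of 16 in B6, 12 and 1 in C3H and 12 and 1 in F1. Camera gave them adjusted p = 0.000227, 4.68e-05 and 0.000382, and 0.656, 0.645 and 0.587 with estimated correlation. Krt7 stood at 3.02, 2.36 and 2.55 and Elf3 at 2.76, 2.66 and 2.61, after 4 higher and 7 lower [4 and 8] in B6, 4 and 7 in C3H and 4 and 7 in F1 at 2 h. Endothelial markers gave 1 higher and 10 lower of 12 in B6, 1 and 7 in C3H and 1 and 10 in F1, called in B6 (adjusted p = 0.023) and F1 (0.031, lost without E2 replicate 2 at 0.0544), with adjusted p = 0.599 and 0.587 with estimated correlation, and the tight junction gene Cldn5 changed by −1.95, −1.35 and −1.63. Smooth muscle markers gave 7 higher and 2 lower of 12 in B6, 6 and 2 in C3H and 9 and 1 in F1, called in F1 (adjusted p = 0.0156, and 0.65 with estimated correlation). The actin gene Actg2 stood at 1.36, 1.36 and 1.55. Stroma markers gave 3 higher and 8 lower of 12 in B6, 2 and 9 in C3H and 2 and 8 in F1. Col6a1 rose (1.85, 1.84 and 1.62) and Fbln1 fell (−1.74, −1.45 and −1.44).

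MHC class II gave 0 higher and 9 lower of 10 in B6, 0 and 5 in C3H and 0 and 7 in F1. H2-Eb1 stood at −1.63, −0.80 and −1.24, and the list was called in B6 (adjusted p = 0.0179, and 0.656 with estimated correlation). T and NK cell markers gave 0 higher and 10 lower of 14 in B6, 0 and 8 in C3H and 0 and 9 in F1, again called in B6 (median −1.44, or −0.92 without vehicle replicate 1, adjusted p = 0.0153, and 0.656 with estimated correlation). The killer cell genes Nkg7 (−1.89, −1.03 and −1.38) and Klrb1c (−1.69, −1.02 and −1.33) fell. Mast cell markers gave 0 higher and 7 lower of 8, 0 and 5, and 0 and 6. The protease gene Cma1 stood at −1.28, −0.72 and −0.89. Interferon-induced genes gave 7 higher and 1 lower [6 and 1] of 21 in B6, 14 and 1 [15 and 1] in C3H and 17 and 1 in F1, called in C3H (adjusted p = 0.0099) and F1 (0.00143), with adjusted p = 0.645 and 0.65 with estimated correlation, and the antiviral genes Oasl1 (2.13, 1.58 and 2.95) and Mx1 (1.39, 1.76 and 2.47) rose. Chemokine genes gave 7 higher and 7 lower [7 and 6] of 28 in B6, 7 and 6 in C3H (median −0.11, mean −0.04, camera upward) and 12 and 4 in F1. The neutrophil attractant gene Cxcl5 rose (5.31, 2.43 and 3.2). Macrophage and dendritic cell markers gave 1 higher and 4 lower [1 and 3] of 14, 4 and 1 [3 and 0], and 3 and 0. Neutrophil markers gave 1 higher and 2 lower of 8, 2 and 1, and 2 and 1. B and plasma cell markers gave 1 higher and 3 lower [1 and 2] of 10, 1 and 1, and 2 and 2 [2 and 0]. Eosinophil markers gave 1 higher and 2 lower of 5, 1 and 2, and 1 and 1 [1 and 0]. Macrophage medians were −0.61, 0.15 and 0.22, with B6 vehicle array means from −0.02 to 1.15. In C3H the medians of the B cell, eosinophil and ciliated cell lists were −0.14, −0.23 and −0.26 with camera upward, as it was for the B and ciliated cell lists of F1 (−0.28 and −0.12).

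Markers of tissue in or beside the uterus moved too. Adipocyte markers gave 0 higher and 2 lower [0 and 1] of 11 in B6 (median −1.78), 1 and 1 [0 and 1] in C3H (0.35) and 0 and 7 in F1 (−2.37). Their vehicle means differed between arrays of one strain (C3H −1.73, −1.81 and 0.94; F1 2.15, 0.31 and 0.86; B6 1.67, 1.77 and 0.74, as log2 differences from the mean of all arrays). Blood cell markers gave 3 higher and 0 lower of 6, 5 and 0, and 6 and 0. Skeletal muscle markers gave 4 higher and 1 lower of 9, 5 and 2, and 6 and 1. Ciliated and oviduct cell markers gave 3 higher and 3 lower of 10, 2 and 3, and 2 and 2 [1 and 1]. Liver transcripts such as albumin, a list added after the data had been seen, fell with E2: of 17, 0 higher and 17 lower in B6, 0 and 16 in C3H and 0 and 14 in F1 at 24 h, with medians of −3.19, −2.51 and −1.93, or −1.82, −0.78 and −0.61 under the scaling nearest 0. Squamous epithelium genes, likewise added, gave 8 higher and 0 lower of 12 in B6, 3 and 1 in C3H, and 6 and 1 in F1, beside the rise of the Sprr genes. Their 24 h arrays were spread (C3H −0.23, 1.67 and −0.54; B6 2.57, 2.33 and 1.23; F1 1.91, 1.09 and −0.47, in order of replicate).

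**Figure D2:**
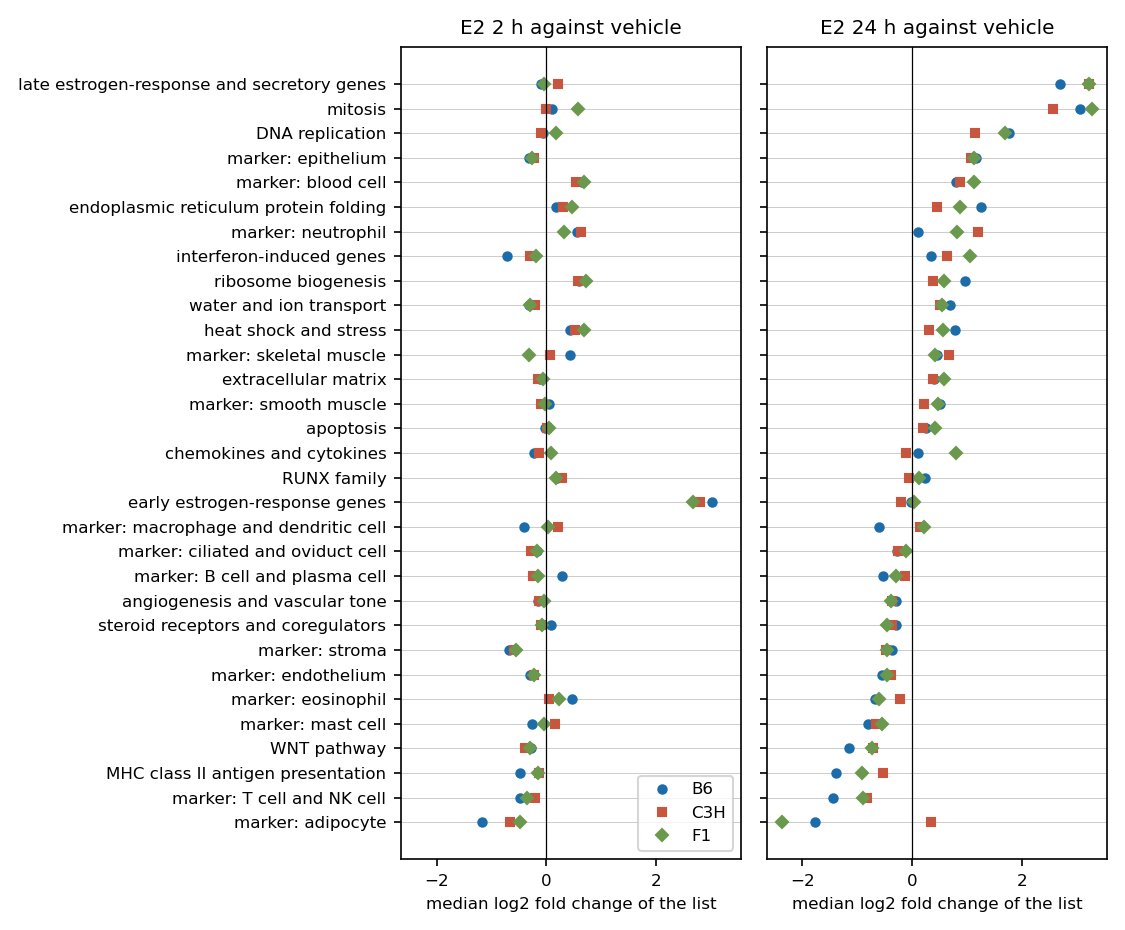
Median log2 change of each of the 31 gene lists against the strain's own vehicle arrays, at 2 h (left) and 24 h (right), with 1 symbol per strain.

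At 24 h E2 changed 14861 genes in B6 (6745 higher and 8116 lower), 14682 in C3H (5920 and 8762) and 14977 in F1 (6952 and 8025). In all 3 strains 11363 genes changed with one sign, 5020 higher and 6343 lower, and r across genes was 0.830 for B6 and C3H, 0.904 for B6 and F1, and 0.858 for C3H and F1. The median change of all genes in C3H was −0.16. Median centring gave 9216 higher and 5942 lower in B6, 7710 and 6359 in C3H and 9098 and 6081 in F1, and the unscaled deposited values 8400 and 6014 in F1. With slide as a fixed term, which rests on B6 E2 2 h replicate 1, B6 had 10642 genes, with medians of 3.57 for mitosis, 1.75 for DNA replication, 2.58 for late estrogen-response genes, −1.47 for MHC class II and −1.69 for T and NK cells. No slide held both groups of one strain for C3H or F1 at 24 h, and with lot as a fixed term F1 had 12301 genes, resting on F1 vehicle replicate 3.

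The strains were next compared without E2. Between C3H and B6 the largest differences were in Trim12a (−7.58 log2 in C3H minus B6, SE 0.42), the receptor phosphatase gene Ptprg (−7.49, SE 0.55) and Thumpd1 (−7.23, with probes that disagreed in sign) on the lower side. The NK cell receptor genes Klra1 and Klra10 were at least 39- and 33.3-fold lower in C3H, and Klra7 (−5.88) and the MHC gene H2-Q8 (−5.43) were lower too. Zfp874a (−5.98) and Cldn34c1 (−5.33) were lower as well, and Zfp939 was at least 13.6-fold lower. On the higher side stood the tissue kallikrein genes Klk1b24 (8.15, SE 0.53), Klk1b3 (7.0), Klk1b26 (6.81), Klk1b21 (6.76), Klk1 (6.58) and Klk1b27 (5.82). The interferon-induced genes Gbp2b (6.78) and Ifi44l (6.7, SE 0.15) and Ica1l (5.99) were higher too. Hbegf, an epidermal growth factor family ligand gene, was higher by 4.04 (SE 0.08) and Sprr2f by 3.17. Whether the probes match the sequence of each strain was not tested.

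T and NK cell markers were lower in C3H than in B6 vehicle uterus, with 1 higher and 8 lower of 14 and a median of −1.05 (camera adjusted p = 9.08e-05), Gzmb at −4.21 and Klrb1c at −2.72. Adipocyte markers gave 0 higher and 8 lower of 11 (median −2.87, adjusted p = 0.00463) and MHC class II genes 0 higher and 4 lower of 10 (−0.53, 0.027), with the adiponectin gene Adipoq at −3.68 (SE 1.04). DNA replication gave 10 higher and 0 lower [14 and 0] of 25 (median 0.25, adjusted p = 0.000878) and smooth muscle markers 9 higher and 0 lower of 12 (0.32, 0.00357), with the replication genes Mcm3 (1.05) and Orc1 (0.94) higher. With estimated correlation the adjusted p was 0.745 for each of these 5 lists. Without B6 vehicle replicate 1 the T and NK median was −0.67 and the MHC class II median −0.12 (adjusted p = 0.44), and without C3H vehicle replicate 1 the latter had adjusted p = 0.0566. Liver transcripts gave 0 higher and 15 lower [0 and 16] of 17, with a median of −1.96, or −1.35 without B6 vehicle replicate 1.

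F1 vehicle uterus differed from B6 in the same kallikreins, with Klk1b24 higher by 6.6 and Klk1b3 by 5.45, and in Gbp2b (5.7), Ifi44l (5.52) and Hbegf (3.3). Among the genes lowest in F1 against B6 were genes of the liver, Sult2a2 (at least 7.47-fold lower), Cyp3a44 (−3.55), Cyp2j5 (at least 6.25-fold) and Cpn2 (at least 4.61-fold), and the 17 liver transcripts gave 0 higher and 15 lower [0 and 16] with a median of −2.52 (−1.52 under the scaling nearest 0). T and NK cell markers gave 0 higher and 7 lower of 14 (median −0.86, adjusted p = 3.69e-07), and interferon-induced genes 0 higher and 8 lower [0 and 17] of 21 (−0.79, 3.69e-07). Mitosis gave 0 higher and 2 lower of 25 (−0.45, 0.000119). MHC class II gave 0 higher and 4 lower [0 and 8] of 10 (−0.74, 0.000843), and macrophage markers 0 higher and 3 lower [1 and 4] of 14 (−0.68, 0.0249). Early estrogen-response genes (0.00843), ribosome biogenesis (0.0403), endoplasmic reticulum folding (0.0242), heat shock (0.0403) and stroma (0.0179) were called upward by camera, with medians of at most 0.12, and each lost its call without 1 of the vehicle arrays (highest adjusted p = 0.0774, 0.0959, 0.177, 0.149 and 0.0545). With estimated correlation these 10 lists had adjusted p = 0.622 to 0.657. Without B6 vehicle replicate 1 the medians were −0.30 for T and NK cells (−1.31 without replicate 2) and −0.30 for interferon-induced genes, both still called. Mitosis (−0.17, adjusted p = 0.125), MHC class II (−0.30, 0.119) and macrophages (−0.29, 0.49) lost their calls without it, macrophages also without F1 vehicle replicate 3 (0.0606).

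Against C3H, F1 vehicle uterus was lower in the immunoglobulin gene Igh (−3.32), and at least 4.56-fold lower in Ralyl and 3.11-fold in the chemokine gene Cxcl11. It was higher in Ptprg (6.58), Trim12a (6.27), Zfp874a (5.08) and Thumpd1 (6.25, with disagreeing probes). Mitosis gave 1 higher and 19 lower [1 and 23] of 25 (median −0.71, adjusted p = 4.14e-07) and DNA replication 0 higher and 10 lower [0 and 17] of 25 (−0.27, 4.14e-07). Smooth muscle gave 0 higher and 6 lower [0 and 9] of 12 (−0.30, 0.000816). Interferon-induced genes gave 0 higher and 2 lower [0 and 0] of 21 (−0.36, 0.0444) and adipocyte markers 6 higher and 0 lower [7 and 1] of 11 (2.74, 0.000824). The interferon call was lost without C3H or F1 vehicle replicate 1 or 3 (adjusted p = 0.0664 to 0.09). With estimated correlation these lists had adjusted p = 0.983.

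In vehicle, 5279 genes differed between C3H and B6 (2863 higher and 2416 lower in C3H), 2734 between F1 and B6 (1131 and 1603) and 3138 between F1 and C3H (1157 and 1981). With slide as a fixed term, which rests on B6 E2 2 h replicate 1 and B6 E2 24 h replicate 3, the C3H and B6 difference held 1655 genes (864 and 791), with medians of −1.52 for T and NK cells, −1.44 for adipocytes, −0.52 for MHC class II, 0.12 for DNA replication and 0.46 for smooth muscle. With lot as a fixed term F1 differed from B6 in 2031 and from C3H in 2484 genes. The split of calls moved with the scaling for F1 against B6 (1389 higher and 1315 lower after normexp and quantile normalisation, 1540 and 1223 after median centring, 529 and 1926 with the unscaled deposited values). The same held for F1 against C3H (1425 and 1428, 1475 and 1591 after quantile normalisation alone, 698 and 2241 unscaled).

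Whether the response to E2 itself depended on strain was tested as the difference of the 2 responses. At 2 h the largest differences between C3H and B6 were in the tissue kallikreins, with a C3H minus B6 response of −6.68 (SE 0.54) for Klk1b3, −6.66 for Klk1b24, −5.8 for Klk1b26, −5.34 for Klk1b21 and −5.1 for Klk1. Of 11 measured kallikrein 1 family genes, 8 had a lower signed response in C3H at 2 h and 9 at 24 h, with medians of −4.86 and −4.61, the same sign under every scaling tried. In vehicle 8 of the 11 were higher in C3H, with a median of 5.82. With E2 the family rose in B6 at 2 h in 11 of 11 genes (median 5.67), while in C3H 6 rose (median 1.01). At 24 h 10 rose and 0 fell in B6 (median 2.84), whereas 2 rose and 7 fell in C3H (−1.76) and 4 rose and 5 fell in F1 (−0.87).

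Hbegf rose in B6 from 0.25 to 3.28 and stood at 4.29 and 3.94 in C3H, a difference of responses of −3.37 (SE 0.11). The WNT ligand gene Wnt9a went from 0.54 to 2.91 in B6, from 0.31 to −1.59 in C3H and from 0.39 to 1.88 in F1, a C3H minus B6 difference of −4.28 (SE 0.12). Signed responses were also lower in C3H for the matricellular gene Ccn2 (−1.55), the vasoconstrictor gene Edn1 (−1.34) and Pgf (−0.81). They were higher in C3H for the serine protease gene Prss29 (3.08), the small G protein gene Rasd1 (1.41) and the endotoxin co-receptor gene Cd14 (1.16). Macrophage and dendritic cell markers gave 1 higher and 0 lower of 14 with a median of 0.71 (camera adjusted p = 0.0016), or 0.43 without B6 vehicle replicate 1 (0.0935) and 0.27 without C3H E2 2 h replicate 1 (0.0576). Chemokines (0.39), interferon-induced genes (0.41), endoplasmic reticulum folding and steroid receptors (−0.20) were called at adjusted p = 0.0422 with 0 genes past the test. With estimated correlation the adjusted p was 0.792 for all 5. The last 4 also lost their calls without B6 vehicle replicate 1 (medians −0.16, −0.13, 0.09 and −0.15), C3H E2 2 h replicate 1, B6 E2 2 h replicate 1 or C3H vehicle replicate 2 (adjusted p from 0.0541), and some without other arrays. Chemokines and interferon stood at 0.70 and 0.64 without B6 vehicle replicate 2 and 0.63 and 0.66 without replicate 3.

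For F1 against B6 at 2 h the response differed in the same kallikreins (Klk1b24 −6.41, Klk1b3 −5.59), in Hbegf (−2.99) and in Edn1 (−1.31), and the insulin-like growth factor binding gene Igfbp1 had a higher response in F1 (3.07). For F1 against C3H the response was higher in F1 for Wnt9a (3.4) and the synapsin gene Syn2 (2.69), and lower for Cd14 (−1.04) and Rasd1 (−0.94). Mitosis genes were called as a list in F1 against B6 (median 0.46, adjusted p = 4.32e-08) and against C3H (0.55, 5.94e-10), with 0 and 0 genes past the test over all genes and 0 and 1 adjusted over the list alone. The first median was 0.27 without B6 vehicle replicate 1 and 0.30 without B6 E2 2 h replicate 2. Camera called 9 lists for F1 against B6 and 3 for F1 against C3H, with adjusted p = 0.922 and 0.91 with estimated correlation. Without B6 vehicle replicate 1, MHC class II, chemokines, interferon and macrophages were no longer among the 9 (medians −0.10, −0.10, −0.05 and 0.08). Ribosome biogenesis lost its call without F1 E2 2 h replicate 2 against B6 (0.06) and without C3H E2 2 h replicate 1 against C3H (0.07).

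At 2 h the response differed between C3H and B6 for 473 genes (173 with a larger and 300 with a smaller value in C3H), between F1 and B6 for 131 (29 and 102) and between F1 and C3H for 50 (20 and 30). The unscaled deposited values gave splits of 150 and 108, 51 and 24, and 14 and 6, and median centring 33 and 59 for F1 against B6. With slide as a fixed term F1 against B6 gave 71 genes, and with lot as a fixed term 83, while F1 against C3H gave 34 with lot. The F1 and B6 count was 344 without F1 E2 2 h replicate 1, 78 without B6 E2 2 h replicate 3, 80 without B6 vehicle replicate 1, 73 without F1 E2 2 h replicate 3 and 77 without F1 vehicle replicate 3. The F1 and C3H count was 31 and 29 without C3H vehicle replicates 1 and 2, 32 and 33 without F1 E2 2 h replicates 2 and 3, and 33 and 32 without F1 vehicle replicates 1 and 2.

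At 24 h the growth-related lists rose less in C3H than in B6. DNA replication gave 0 higher and 23 lower of 25, with a median difference of −0.75 (camera adjusted p = 2.65e-16, and 0.21 with estimated correlation), including Orc1 (−1.39), Uhrf1 (−1.36) and Cdc6 (−1.28). The C3H minus B6 vehicle median of that list was 0.25. Ribosome biogenesis gave 0 higher and 18 lower [0 and 21] of 25 (median −0.53, adjusted p = 1.71e-09, and 0.503 with estimated correlation), including Rrp12 (−1.15), Nolc1 (−0.93) and Rrs1 (−0.75). Endoplasmic reticulum folding gave 0 higher and 11 lower [0 and 12] of 22 (−0.50, 0.000382, and 0.72 with estimated correlation), including the chaperone genes Hspa5 (−1.01), Manf (−1.13) and Creld2 (−1.16). Mitosis gave 1 higher and 4 lower [1 and 5] of 25 (−0.61, 0.00873, and 0.767 with estimated correlation), with Mki67 (−0.80) and Cdc20 (−0.76) on the lower side and Bub1b (2.09) on the higher. The mitosis call was lost without B6 vehicle replicate 3 (−0.47, adjusted p = 0.0881) or C3H E2 24 h replicate 1 (−0.58, 0.117).

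Camera called 4 immune lists with higher response values in C3H than B6 at 24 h, resting partly on B6 vehicle replicate 1. MHC class II genes had a median difference of 0.84 (1 higher and 0 lower [0 and 0] of 10, adjusted p = 0.00071), or 0.40 without that array (0.018). Macrophage markers had 0.70 (4 higher and 0 lower of 14, 0.000579), or 0.30 (0.0377). T and NK cell markers had 0.66 (3 higher and 1 lower of 14, 0.00559), or 0.29 with the call lost (0.169). Interferon-induced genes had 0.29 (0 higher and 0 lower of 21, 0.034), turning to −0.09 (0.48), and were not called without B6 E2 24 h, C3H E2 24 h or C3H vehicle replicate 2 either. Without the other B6 vehicle arrays they stood at 0.44 and 0.51. Adipocyte markers (2.12, 1 higher and 0 lower of 11, 0.00873), endothelium (3 higher and 0 lower [4 and 0] of 12, 0.0291) and the WNT pathway (3 higher and 0 lower [2 and 0] of 23, 0.0138) were called as well. Adipocytes lost the call without B6 vehicle replicate 1 (adjusted p = 0.0545; 3.33 without C3H vehicle replicate 3) and endothelium without B6 E2 24 h replicate 1 (0.0545; medians 0.05 to 0.14), and the WNT median was 0.12 without B6 vehicle replicate 3. With estimated correlation none of these 7 lists was called (adjusted p = 0.72 for MHC class II and 0.504 for WNT). Cd14 (1.34) and the macrophage growth factor receptor gene Csf1r (1.11) responded more in C3H, as did Ltf (1.59), the defence gene Apol7c (2.95) and the intestinal keratin gene Krt20 (3.04).

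Sprr2f (−2.59, from a higher vehicle level), Sprr1a (−1.67) and Igf1 (−0.77) rose less in C3H. The squamous list median difference was −0.90 (0 higher and 2 lower of 12). The signed response was also lower in C3H for genes called as rising in B6 and not in C3H: the endothelial genes Esm1 (−1.67, falling in C3H) and Apln (−1.02), the chemokine gene Ccl20 (−3.07), the cartilage gene Crtac1 (−5.15, SE 0.47) and the kallikreins Klk1b3 (−6.61), Klk1b24 (−5.28) and Klk1b26 (−5.14), which fell in C3H.

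At 24 h camera called 10 lists for F1 against B6, each with adjusted p = 0.623 with estimated correlation. Ribosome biogenesis gave 0 higher and 0 lower [0 and 13] of 25 (median −0.28, adjusted p = 9e-07) and heat shock 0 higher and 2 lower [0 and 6] of 13 (−0.33, or −0.22 without B6 E2 24 h replicate 2, 0.00768). DNA replication (−0.15, 0.0349) and endoplasmic reticulum folding (−0.27, 0.0279, or −0.14 without B6 E2 24 h replicate 3) were lower with 0 genes each past the test [0 and 2], and their calls were lost without 5 and 6 of the 12 arrays in turn (adjusted p up to 0.33 and 0.134). Interferon-induced genes (0.76, 1.57e-07), macrophages (0.74, 0.000382), T and NK cells (0.53, 0.00131), MHC class II (0.47, 0.0138) and mitosis (0.33, 0.00129) were higher as lists, with 1 mitosis gene and 0 others past the test [1 mitosis, 2 interferon and 1 macrophage gene]. Without B6 vehicle replicate 1 these stood at 0.31, 0.43, 0.09, 0.09 and 0.09, the last 3 not called (adjusted p = 0.416, 0.59 and 0.24). MHC class II also lost its call without F1 E2 24 h replicate 3 (0.31) and stood at 0.72 without replicate 2 and 0.74 without B6 vehicle replicate 2, and mitosis at 0.54 and 0.22 without B6 and F1 vehicle replicate 3. The WNT pathway (0.11, 0.022) lay between 0.05 and 0.20, and its call was lost without 4 arrays in turn. Sprr2f rose less (−2.61) and Bub1b more (1.5) in F1 than in B6, Esm1 (−1.68) and Klk1b24 (−5.76) rose in B6 and fell in F1, and Hbegf fell further in F1 (−1.27).

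Against C3H, DNA replication gave 17 higher and 0 lower [24 and 0] of 25 (median 0.57, adjusted p = 4.72e-22, and 0.0693 with estimated correlation), including Uhrf1 (1.61), Mcm10 (1.47) and Cdc6 (1.46). Mitosis gave 6 higher and 0 lower [23 and 1] of 25 (0.88, 1.89e-11, and 0.785 with estimated correlation), including Ccnb1 (1.55) and Mki67 (1.12). Runx1 also responded more (0.61, with disagreeing probes). Adipocytes were lower (−2.71, 0.0011), mirroring a vehicle median of 2.74. Ribosome biogenesis (0.24, 0.000592), endoplasmic reticulum folding (0.25, 0.00503), smooth muscle (0.25, 0.0161) and interferon-induced genes (0.44, 0.0386) were higher. Of their genes 1, 3, 0 and 1 passed the test [4, 3, 1 and 1]. Steroid receptors (−0.08, 0.047, or −0.14 without F1 vehicle replicate 1) were lower. With estimated correlation these 6 lists had adjusted p = 0.785 to 0.99. Smooth muscle, interferon and steroid receptors lost their calls without 2, 7 and 8 arrays in turn (adjusted p up to 0.0633, 0.182 and 0.165).

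At 24 h the response differed for 4095 genes between C3H and B6 (1262 with a larger and 2833 with a smaller value in C3H), for 415 between F1 and B6 (193 and 222) and for 809 between F1 and C3H (657 and 152). Normexp with quantile normalisation gave 1566 and 2266 for C3H against B6 and 355 and 210 for F1 against C3H, and quantile normalisation alone 1504 and 2176, and 440 and 188. The unscaled deposited values gave 131 and 36 for F1 against B6 and 753 and 49 for F1 against C3H. The C3H and B6 contrast cannot be fitted with slide as a fixed term, and with lot as a fixed term F1 differed from B6 in 116 and from C3H in 206 genes. The F1 and B6 count was 248 and 215 without B6 E2 24 h replicates 2 and 3, 228 and 212 without F1 E2 24 h replicates 1 and 3, and 175 and 249 without F1 vehicle replicates 1 and 2. The F1 and C3H count was 1932, 336 and 390 without C3H E2 24 h replicates 1, 2 and 3, and 351 and 376 without C3H vehicle replicates 1 and 3. It was 424 and 471 without F1 E2 24 h replicates 1 and 3, and 458 and 428 without F1 vehicle replicates 1 and 2.

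**Figure D3:**
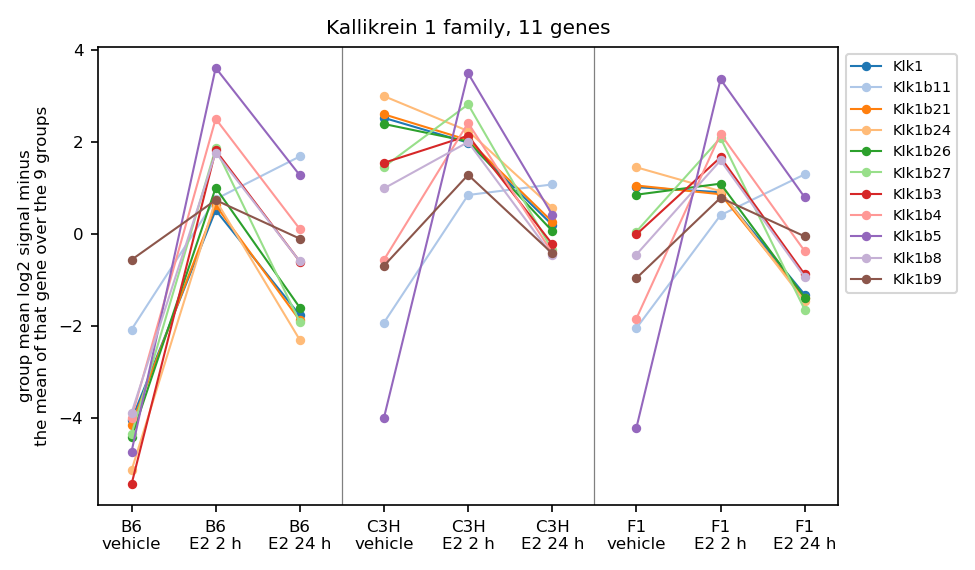
Group mean log2 signal of 11 kallikrein 1 family genes, each minus that gene's mean over the 9 groups, in vehicle, E2 2 h and E2 24 h (n = 3 arrays per point).

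Response size was scored on genes called in the strain not compared. At 24 h C3H scored 1.28 ± 0.0327 (SD, n = 3) and B6 1.53 ± 0.0347 over 5014 genes called in F1, a difference of −0.255 or 83.4% of B6 (exact permutation p = 0.02). Genes that rose in F1 scored 1.27 in C3H and 1.61 in B6 (difference −0.336, exact permutation p = 0.02) and genes that fell 1.28 and 1.48 (−0.198, p = 0.045). F1 scored 1.44 ± 0.0528 against 1.23 ± 0.0129 in C3H over 5312 genes called in B6 (0.211, 117% of C3H, exact permutation p = 0.01). Rising genes gave 0.310 (p = 0.005, the smallest these permutations can give). F1 and B6 scored 1.48 ± 0.0568 and 1.48 ± 0.0575 over 4154 genes called in C3H (−0.00467, exact permutation p = 0.98). Genes called in one parent may favour F1 over the other. At 2 h the differences were 0.0614 for C3H minus B6 (p = 0.485), 0.142 for F1 minus B6 (p = 0.265) and 0.0974 for F1 minus C3H (p = 0.205), each by exact permutation. The last was 0.157 (exact permutation p = 0.02) without F1 E2 2 h replicate 1. Normexp with quantile normalisation gave −0.195 (exact permutation p = 0.055) for C3H minus B6 at 24 h.

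**Figure D4:**
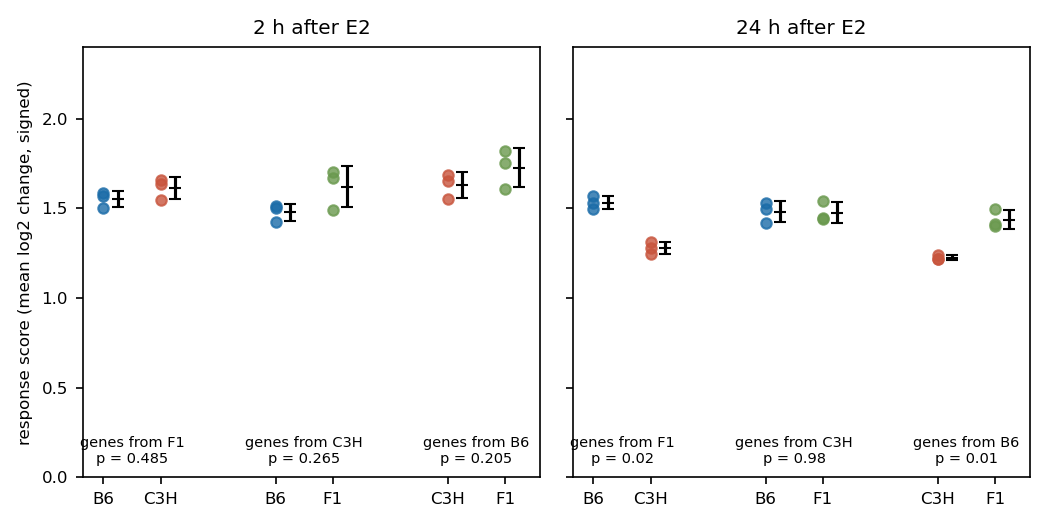
Response score of each E2 array, the mean signed log2 change from the strain's vehicle mean, at 2 h (left) and 24 h (right) for the 3 pairs of strains, with the mean and SD (n = 3) beside the points and the exact permutation p.

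The position of F1 between its parents was taken over genes that differed between C3H and B6, where 0 is B6 and 1 is C3H. The slope was 0.614 at 2 h (473 genes), 0.404 at 24 h (4095 genes) and 0.509 in vehicle (5279 genes), with SDs over single F1 arrays of 0.0340, 0.0206 and 0.0199. After normexp and quantile normalisation it was 0.544 at 24 h, past the midpoint, and 0.533 in vehicle. Simulated F1 data at the midpoint gave 0.499, 0.5 and 0.499, those at B6 0.125, 0.101 and 0.0356, and those at C3H 0.872, 0.9 and 0.964. The F1 value lay between the parents for 427 genes (90.3%) at 2 h, 3578 (87.4%) at 24 h and 4602 (87.2%) in vehicle.

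**Figure D5:**
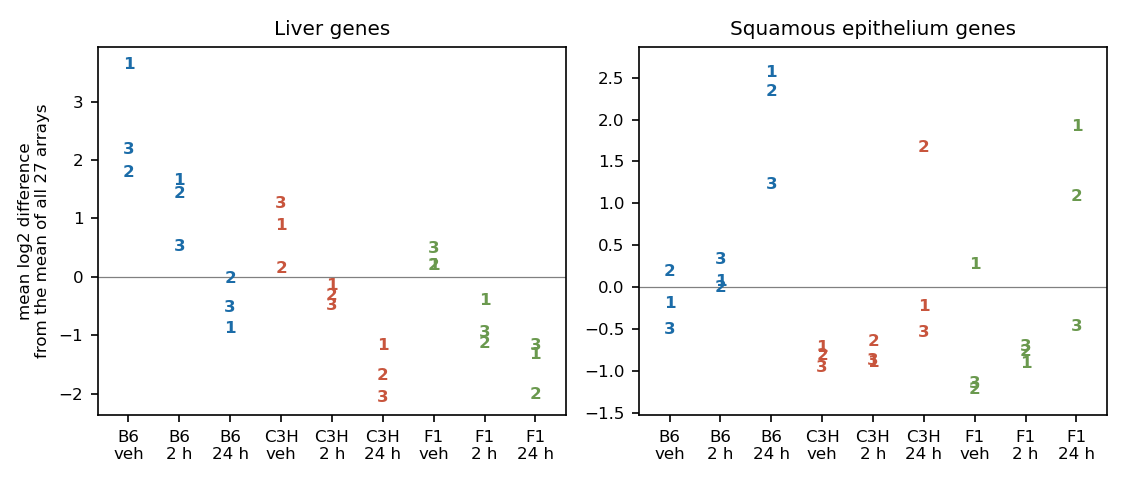
Mean log2 difference from the mean of all 27 arrays for the liver list (left, 17 genes) and the squamous epithelium list (right, 12 genes), with each array drawn as its replicate number. B6 vehicle arrays stand at 3.64, 1.79 and 2.18 on the liver list, and C3H vehicle arrays at 0.88, 0.15 and 1.26.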

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

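Tests chosen only after the results were seen are those of slide, scaling alone, probe mismatch, paralogs and liver RNA. So are those without the 3 arrays standing apart and of lists without 1 array. Results below were picked because a test of the difference between 2 strains' E2 responses passed its threshold. The 24 h scores of C3H minus B6 (−0.255) and F1 minus C3H (0.211, on B6-called genes) passed exact permutation tests.

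In C3H the 2 h log2 response was lower than in B6 for Klk1b3 (−6.68), Klk1b24 (−6.66), Klk1b26 (−5.8), Klk1b21 (−5.34), Klk1 (−5.1), Klk1b27 (−4.86), Klk1b8 (−4.66), Wnt9a (−4.28), Klk1b4 (−3.54), Hbegf (−3.37), Ccn2 (−1.55), Edn1 (−1.34) and Pgf (−0.81). It was higher for Extl1 (3.92), Prss29 (3.08), Lrtm1 (2.93), Lect2 (2.53), H2ap (2.36), C2cd4b (2.15), Rasd1 (1.41) and Cd14 (1.16). With a group not well above background, values of C3H minus B6 were Uts2 (3.43), Rhd (3.18), Gfap (3.08) and Otud7a (2.87). Probes of Extl1 and Gfap disagreed in sign there.

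In F1 the 2 h log2 response was lower than in B6 for Klk1b24 (−6.41), Klk1b3 (−5.59), Klk1b26 (−5.19), Klk1b21 (−4.97), Hbegf (−2.99) and Edn1 (−1.31). It was higher for Extl1 (3.3) and Igfbp1 (3.07). With a group not well above background, values of F1 minus B6 were Otud7a (2.93) and Prss29 (2.48). Probes of Extl1 and Klk1b26 disagreed in sign there. In F1 the 2 h log2 response was lower than in C3H for Olfr339 (−2.57), H2ap (−2.54), Olfr741 (−2.01), Cd14 (−1.04) and Rasd1 (−0.94). It was higher for Wnt9a (3.4) and Syn2 (2.69). With a group not well above background, values of F1 minus C3H were Khdc1a (2.48), Prl (2.05) and Rhd (−2.34).

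In C3H the 24 h log2 response was lower than in B6 for Klk1b3 (−6.61), Klk1b24 (−5.28), Crtac1 (−5.15), Klk1b26 (−5.14), Klk1b8 (−4.77), Klk1 (−4.61), Klk1b21 (−4.61), Klk1b27 (−4.25), Ccl20 (−3.07), Sprr2f (−2.59), Esm1 (−1.67), Sprr1a (−1.67), Orc1 (−1.39), Uhrf1 (−1.36), Cdc6 (−1.28), Creld2 (−1.16), Rrp12 (−1.15), Manf (−1.13), Apln (−1.02), Hspa5 (−1.01), Nolc1 (−0.93), Mki67 (−0.80), Igf1 (−0.77), Cdc20 (−0.76) and Rrs1 (−0.75). It was higher for Krt20 (3.04), Apol7c (2.95), Gm9758 (2.87), Bub1b (2.09), Ltf (1.59), Cd14 (1.34) and Csf1r (1.11). With a group not well above background, values of C3H minus B6 were Etnppl (4.88), Jhy (3.45), Uts2 (3.34), Crp (3.26), Defb14 (3.16), Slfn1 (2.94), Pira1 (2.85), Krt6a (−5.49) and Trim15 (−5.77). After normexp and quantile normalisation Jhy stood at −0.27.

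In F1 the 24 h log2 response was lower than in B6 for Klk1b24 (−5.76), Klk1b3 (−5.72), Klk1b26 (−5.05), Klk1b21 (−4.73), Sprr2f (−2.61), Esm1 (−1.68) and Hbegf (−1.27). It was higher for Bub1b (1.5). With a group not well above background, values of F1 minus B6 were Smlr1 (4.53), Jhy (3.4), Crp (3.21) and Cpn2 (3.02). After normexp and quantile normalisation Jhy stood at −0.14. Probes of Klk1b26 disagreed in sign there. In F1 the 24 h log2 response was lower than in C3H for Eps8l1 (−1.91). It was higher for Crtac1 (4.51), Cxcl1 (3.4), Uhrf1 (1.61), Ccnb1 (1.55), Mcm10 (1.47), Cdc6 (1.46), Mki67 (1.12) and Runx1 (0.61). With a group not well above background, values of F1 minus C3H were Trim15 (4.2), Olfr61 (3.96), Rhd (−1.77), Etnppl (−2.51) and Uts2 (−2.71). Probes of Runx1 disagreed in sign there.

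For E2 against vehicle and strains in vehicle, 3 against 3 arrays make 10 splits, too few for a share under 0.05. With E2 at 2 h the real counts were 12298, 13190 and 12947 in B6, C3H and F1 and the highest others 2, 0 and 1. With E2 at 24 h they were 14861, 14682 and 14977 against 6, 105 and 2. In vehicle they were 5279, 2734 and 3138 against 560, 1 and 1. For differences of responses, 100 of 200 splits were drawn. At 2 h 10 splits for C3H against B6, 12 for F1 against B6 and 10 for F1 against C3H gave counts as large as the real 473, 131 and 50, the real split included, with highest others of 8333, 6760 and 6574. At 24 h 6, 10 and 6 splits were as large as 4095, 415 and 809, with highest others of 7860, 5141 and 4507. By these shares chance is not excluded. All other splits as large kept strains whole within a treatment and so hold the strain difference. Among 85 splits mixing strains 0 were as large. Highest counts were 115, 2 and 2 at 2 h and 60, 4 and 3 at 24 h. Mixing strains or treatments adds real differences to the spread, so low counts do not show what chance gives.

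The first pattern is the smaller 24 h response of C3H. Without the 3 arrays that stood apart the score difference was −0.340, which argues against those arrays as its source. Scaling alone is argued against by −0.270 with quantile normalisation (exact permutation p = 0.025), −0.281 with median centring and −0.265 unscaled (0.02 each), while background correction and scaling changed together stay open, as normexp with quantile normalisation gave −0.195 (0.055). Slide cannot be told apart from strain, and within-slide r (0.00709) misses effects shared by a group's arrays. A higher starting level in C3H vehicle may account for 31.9% of the difference (21.5% to 45.7% leaving out 1 array), and a strain difference in the response itself stays open and untested beyond this.

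The second pattern is the kallikrein 1 family, higher in C3H vehicle, with an E2 response that is lower at 2 h and a fall at 24 h (median −1.76, against 2.84 in B6). Probe mismatch would shift all treatments of a strain alike. The 2 h responses the family was picked on differed by a median of −4.86 (−5.13 to −4.72 leaving out 1 array). This is no independent test of mismatch. For estrogen left in C3H vehicle animals, the vehicle difference over 3878 genes was 4.68% of the 2 h F1 response (3.83% to 6.11%). As these genes were picked at 2 h, lasting estrogen stays open. Signal shared by paralogs stays open, as Klk1b5 (0.74 log2, SE 0.29, C3H minus B6 vehicle) differed less but in the same direction. Klk1b11 (0.15, SE 0.22) and Klk1b9 (−0.13, SE 0.24) were at low signal. Strain regulation of the locus is a candidate explanation that was not tested further.

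The third pattern is that liver transcripts were highest in B6 vehicle and fell with E2. One shift per array took 71.4% of the within-group variance of the 17 measured liver genes, against a median of 7.61% over 1000 random lists and an upper tail value of 13.0%, consistent with liver RNA carried into whole-uterus samples. That test is not specific, since mitosis (72.1%), interferon-induced genes (72.3%), MHC class II (68.7%) and adipocyte markers (69.4%) gave similar shares. Slide stays open, since the 24 h median of −2.42 in B6 with slide as a fixed term rests on 1 array, and B6 vehicle replicate 1 as the only source is argued against by a vehicle median of −1.91 for F1 minus B6 without it. Alb stood at 2.83, 1.39 and −0.58 in B6 vehicle, 2 h and 24 h and Ahsg at 2.26, 0.93 and −0.93, none of the 17 genes is on another list, and expression of these genes by the uterus itself stays open and was not tested.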

How the results depend on the processing

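Of tests chosen after seeing the results, this part holds those without the 3 arrays standing apart, within slides and of lists without 1 array. Every number of genes kept its order of size, within 1.5 times, with outlier spots kept, with the mean over probes, with trend and robust fitting and with slide as a random block. Normexp with quantile normalisation gave 785 genes for C3H against B6 at 2 h (344 higher and 441 lower), 199 for F1 against B6 and 102 for F1 against C3H at 2 h, and 688 for F1 against B6 at 24 h. It gave a 24 h C3H minus B6 score of −0.195 and F1 positions of 0.544 at 24 h and 0.533 in vehicle. Quantile normalisation gave 84 genes for F1 against C3H at 2 h and F1 positions of 0.578 at 2 h and 0.447 at 24 h. Median centring gave 253 genes for F1 against B6 at 24 h. The unscaled deposited values gave 258, 75 and 20 genes for C3H against B6, F1 against B6 and F1 against C3H at 2 h, and 2276 (820 higher and 1456 lower) and 167 for C3H and F1 against B6 at 24 h.

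No filter on dim probes gave 250 genes for F1 against B6 at 24 h. Genes well above background on all 27 arrays, a smaller set, gave 33 for F1 against C3H at 2 h and F1 positions of 0.464 at 24 h and 0.539 in vehicle. Array weights gave 10458, 6022 and 7698 genes in vehicle for C3H against B6, F1 against B6 and F1 against C3H, 2025, 885 and 554 in response at 2 h and 8501, 2300 and 5376 at 24 h. Models of only the strains compared, with fewer arrays to estimate the spread, gave 71 and 182 genes for F1 against B6 at 2 h and 24 h. Slide as a fixed term gave 1655 genes for C3H against B6 in vehicle and 71 for F1 against B6 at 2 h, and it was not run for the 10 contrasts it cannot estimate. Lot as a fixed term gave 83 and 116 genes for F1 against B6 at 2 h and 24 h and 206 for F1 against C3H at 24 h. A 2-fold minimum, which by construction removes small changes, left 3428, 3856 and 3878 genes with E2 at 2 h in B6, C3H and F1 and 5312, 4154 and 5014 at 24 h, 1512, 731 and 821 in vehicle, and 180, 56 and 31 in response at 2 h and 933, 96 and 426 at 24 h. Without the arrays that stood apart, F1 against C3H gave 123 genes at 2 h and 2300 at 24 h.

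Of 107 list calls 3 held with an estimated correlation. Fry lost 51 calls and made 85 others. Calls lost and made were 14 and 13 with normexp and quantile normalisation, 16 and 10 with quantile alone, 7 and 5 with median centring, 10 and 15 unscaled, 1 and 20 without the filter, 7 and 1 with the filter over all arrays, 1 and 5 with the replicate block and 18 and 18 without the arrays that stood apart. With each array left out in turn 70 calls held throughout and 37 were lost at least once, 21 of them without B6 vehicle replicate 1. Camera turned without the arrays that stood apart for chemokines of C3H minus B6 at 2 h (median −0.13). It turned there and without single arrays (range after the semicolon) for interferon-induced genes of C3H minus B6 at 2 h (−0.24; −0.13 to 0.66) and 24 h (−0.10; −0.0919 to 0.51), for the list interferon-induced genes, F1 vs B6, response at 2 h (−0.0545; −0.0545 to 0.61), and for MHC class II of F1 minus B6 at 2 h (−0.10; −0.0994 to 0.61). Leaving out 1 array in turn gave 73 to 344 genes for F1 against B6 and 29 to 70 for F1 against C3H at 2 h, 175 to 506 and 336 to 1932 at 24 h, and a 2 h score difference of F1 minus C3H of 0.0490 to 0.157.

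Of the 6 correlations between strains 5 fell by over 0.05 without the filter (correlation of responses at 24 h, B6 and C3H, 0.761), and 2 rose after normexp and quantile normalisation (0.882 for this pair) and 1 with the filter over all arrays. Of 1288 values of named genes, calls lost and made numbered 55 and 12 with normexp and quantile normalisation, 79 and 6 unscaled and 9 and 42 with array weights. Signs turned for single genes. Jhy stood at −0.27 (C3H minus B6) and −0.14 (F1 minus B6) at 24 h and Fkbp5 at 0.09 in C3H against B6 vehicle after normexp and quantile normalisation, and Fkbp5 at 0.17 after quantile normalisation. Nnt stood at 0.04 for E2 2 h in F1 with the unscaled values. Thumpd1 stood at 0.31 (C3H minus B6) and −0.10 (F1 minus C3H) in vehicle over probes above background on all arrays. With the mean over probes Edem1 (−0.10), Hyou1 (−0.34) and Nop56 (−0.09) turned in C3H against B6 vehicle, Runx3 for E2 24 h in F1 (−0.15) and Runx1 for F1 against C3H vehicle (0.58), where the probes averaged are the change made. With slide as a fixed term Hyou1 (−0.20) and Polr1b (0.18) turned in C3H against B6 vehicle.

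Same-numbered arrays of one strain did not deviate together, with 5 of 27 pairs over r = 0.1 (−0.124 to 0.169, median 0.00446). The replicate block gave 4157 genes for C3H against B6 at 24 h and 12379 for E2 2 h in B6, and no count moved by 1.5 times. The median change of all genes lay over 0.1 from 0 also with median centring (0.18 for B6 and 0.17 for F1 at 24 h, −0.10 for the C3H minus B6 difference), with the unscaled values (0.13 and 0.14 for F1 at 2 h and 24 h, 0.12 for the F1 minus B6 difference at 2 h, −0.10 for F1 against C3H vehicle), without the filter (−0.15 and −0.21 for C3H, −0.11 for the C3H minus B6 difference at 24 h), with array weights (−0.11 for F1 at 2 h, −0.19 for C3H at 24 h), with slide or lot terms (−0.13 for F1 at 2 h), and without the arrays that stood apart (−0.21 for C3H at 24 h).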

Other observations

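No hypothesis beyond the 3 patterns weighed above was tested. Genes changed oppositely in B6 and C3H numbered 60 at 2 h and 259 at 24 h, each strain against its own vehicle arrays. At the genes that differed between C3H and B6, F1 differed at adjusted p under 0.05 only from B6 for 221 of 473 genes at 2 h, only from C3H for 143, from both for 66 and from neither for 43. At 24 h these were 1081, 1236, 190 and 1588 of 4095.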
